A study of Mus musculus with 2 samples.

How the data were processed

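Transcripts were counted in 2 RNA libraries, 1 from Gata2Venus-negative and 1 from Gata2Venus-positive CD31+ KITint cells of the mouse aorta at embryonic day 11. Per the labels' protocols, RNA was extracted using Ambion's mirVana kit and turned into cDNA by SMARTER, and Illumina libraries were made in the usual way. SMARTER copies and amplifies cDNA by PCR, and no molecular identifiers are named, so repeated reads of a molecule count more than once. TopHat, Cufflinks and HTSeq are named per the submitters' processing notes, with genome build mm10. Their versions, the gene annotation and the use of strand are not given in the sources used here, so reads of overlapping or antisense genes cannot be told apart, and genes with near-identical copies (ribosomal protein genes, globins, Gapdh) are uncertain.

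The values deposited by the authors are whole-number counts per gene symbol, not normalized, in 1 table per library, with 24062 genes and 5 further rows for reads assigned to no gene. Of all counts in the table, 45.5% in the negative and 48.2% in the positive library were in the row for alignments that are not unique, 5.93% and 7.996% in the row for no feature, and 0.474% and 0.412% in the row for ambiguous reads, and the rows for low quality and for not aligned held 0. These rows were left out of library sizes and of every comparison. Counts in genes totalled 10135400 and 9715131. A count of 0 allows a level of up to 3 counts, 0.288 CPM in the negative and 0.317 CPM in the positive library.

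Groups were taken from the labels. With 1 library per group, no test between conditions was possible, and a fixed rule of size replaced it. Counts were scaled by edgeR's TMM factors (1.03 and 0.974; edgeR 4.0.16 in R 4.3.3) on the total over genes. A gene was past the rule when it had at least 10 CPM and 50 counts in the library where it was higher and the exact 95% interval of its ratio between the libraries (Clopper-Pearson, given the gene's total) lay wholly beyond 2-fold. Levels have exact Poisson intervals. Intervals cover counting error only. Where a library had 0 counts, the ratio given as "at least" was computed with 3 counts in that library. Its exact interval reaches closer to equal expression, as for Deptor, from a log2 ratio of 7.94 where 3 counts give 8.24. Genes with 1 to 3 counts keep their ratio and interval.

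The choices of this paragraph were made before the data were examined, as were the rule of size, the gene lists and the alternatives not said to be added. For 32 lists of lineage genes, pathways and quality markers, the median log2 ratio of the members with at least 20 counts over both libraries was set against 10000 random lists of the same size, each gene drawn from the 200 nearest to a member in mean expression. A percentile under 2.5 or over 97.5 is said to stand apart. Intervals of a list's median come from the order of its members' ratios (binomial, 95%), and genes are not independent replicates. Genes were named by rule: Gata2, Kit and Pecam1 first, then the 12 genes in each direction past the rule whose interval lay farthest from equal expression, leaving out predicted, ribosomal protein, mitochondrial and small RNA genes, then up to 4 members of each list past the rule by the same ranking, with the 2 most abundant members where fewer than 2 passed, and lists of under 9 genes in full. Other genes are said to have been named after their values were seen. Some genes that the rule names are not reported here, though they remain in the counts and medians. Coordinates come from the GENCODE vM21 annotation of mm10, to which 22708 genes (94.4%) matched by symbol.

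Alternatives were scaling by total counts, by DESeq2 1.42.0 size factors, without the 100 most abundant genes, and without predicted, ribosomal, mitochondrial and small RNA genes, filters of 1 CPM and 10 counts, of 50 CPM and none, an interval beyond 4-fold, a 2-fold ratio without the interval, the deeper library thinned to the shallower total, an assumed coefficient of variation of 0.4 between libraries, list members with at least 100 counts, and 0.5 counts added to every gene. Leaving out genes at 3 or fewer counts in one library, and list members under a mean of 50 CPM, were added after seeing the data. Scaling by total counts moved the median log2 ratio of all tested genes by 0.08, and the other scalings moved it by less.

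The steps were tested on simulated data for this comparison, with counts for all 24062 genes and 200 of them changed. Simulated counts held counting error alone, and the changed genes were drawn from those with at least 200 counts over both libraries. Spread between libraries beyond counting error was not simulated, so the calls and coverage below say nothing about it. The rule called 69 of 71 genes changed 3-fold, 66 of 66 changed 4-fold and 63 of 63 changed 8-fold, and 0 unchanged genes. Intervals covered the true ratio for 95.6% of 12532 genes. Of 100 lists of unchanged genes 6 stood apart, and 100 of 100 lists shifted by a log2 ratio of 1 did. Computation used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1.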

Results

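RNA from CD31+ KITint cells of the mouse aorta at embryonic day 11, which the labels call haematopoietic progenitor cells, was measured by sequencing. The cells came from C57BL6 embryos carrying Gata2Venus, a fluorescent reporter transgene for the haematopoietic transcription factor Gata2, and had been sorted on that reporter. The Gata2Venus-negative group held 1 library with 10135400 counts in genes and the Gata2Venus-positive group 1 library with 9715131, over 24062 genes. At least 1 count was found for 12392 genes in the negative and 12709 in the positive library. The series is about progenitors that do not depend on Gata2, and its comparison asks how the transcriptomes of reporter-negative and reporter-positive progenitors differ. With 1 library per group no difference has a replicate check and no p-value is given. Each comparison is one of these libraries, not of the conditions, and the 95% intervals cover counting error only. They take each read as an independent draw. Amplified reads without molecular identifiers are not independent molecules, so the intervals can be too narrow.

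In the Gata2Venus-negative library, genes of megakaryocytes, macrophages and endothelium were lower and genes of mesenchyme and smooth muscle were higher than in the Gata2Venus-positive library. Runx1, a transcription factor required for blood cells to emerge from endothelium, was 15.9-fold lower in the negative library (log2 ratio of negative over positive −3.99, interval −4.70 to −3.35). Pdgfra, a growth factor receptor of mesenchymal cells, was 7.81-fold higher there (log2 ratio 2.96, interval 2.80 to 3.13). Of the 200 genes nearest to each in mean expression, 12.5% differed by as much as Runx1 and 0.5% by as much as Pdgfra. A gene was counted when it reached 10 CPM and 50 counts in the library where it was higher and the interval of its ratio lay wholly beyond 2-fold. By this rule of size 1582 of 10381 genes (15.2%) were higher in the negative library and 1545 (14.9%) in the positive library. The spread of the log2 ratios was taken as an SD from the interquartile range, over genes with more than 3 counts in both libraries. It was 1.40 for genes of 10 to 20 CPM and 0.46 for genes above 500 CPM, and leaves out genes at or near 0 in one library. The median counting errors at those levels were 0.19 and 0.024. For other genes past the rule, the share of the 200 nearest genes that differed by as much varied. It was, for example, 0.5% for Hhip, 36% for Hoxc6 and 45% for Rpl12. With an assumed coefficient of variation of 0.4 between libraries, 641 genes were past the rule on the negative side and 683 on the positive side.

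**Figure D1:**
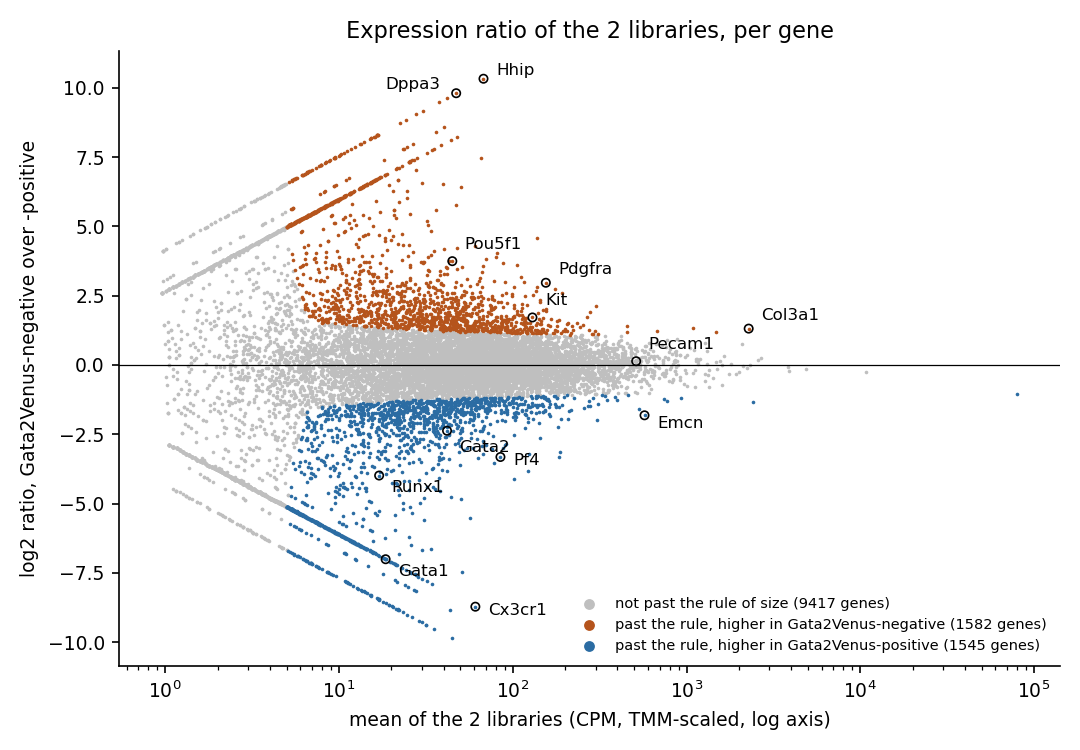
Each point is a gene with at least 20 counts over both libraries, at its mean expression in CPM (log axis) and its log2 ratio of the Gata2Venus-negative over the Gata2Venus-positive library, with a library at 0 counts put at 3 counts. Coloured points are the 1582 genes past the rule of size that were higher in the negative and the 1545 that were higher in the positive library; the diagonal bands are genes with 0 to a few counts in one library.

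The sort markers were examined first, as a check of the labels. Gata2 (chromosome 6, 88193891 to 88207032, mm10) had 141 counts in the negative and 664 in the positive library, or 13.5 CPM (interval 11.4 to 15.97) and 70.2 CPM (interval 65.0 to 75.8). It was thus 5.18-fold lower in the negative library (log2 ratio −2.37, interval −2.65 to −2.11), the direction the labels give, and it was detected in both. Among the 200 genes nearest to Gata2 in mean expression, 5.5% differed by as much. Kit (chromosome 5, 75574916 to 75656722), the receptor used for the KITint gate of both groups, was 3.28-fold higher in the negative library, at 199 against 60.7 CPM (log2 ratio 1.71, interval 1.58 to 1.85). Pecam1 (chromosome 11, 106654217 to 106750628), which encodes CD31, was at 537 and 489 CPM and not past the rule (log2 ratio 0.13, interval 0.08 to 0.19).

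The genes that led the rule of size were present in one library and at or near 0 in the other. Hhip (chromosome 8, 79965851 to 80058006), a Hedgehog-binding membrane protein, had 1412 counts in the negative and 1 in the positive library (log2 ratio 10.32, interval 7.84 to 15.63). Dppa3, a gene of germ cells and early embryos, had 983 counts and 1, and the metalloprotease gene Adamts15 had 867 and 1. Deptor, an inhibitor of mTOR, had 999 counts in the negative library and 0 in the positive, which puts it at least 303-fold higher when 0 is set to 3 counts in that library. The matrix protein gene Thbs2 (915 counts), Ap3b2 (803), Ak5 (736), Ankzf1 (712), Katnal1 (583), Aldh6a1 (562), Fam171b (549) and Adamts7 (537) were likewise at 0 in the positive library. In the other direction, Trim16 (chromosome 11, 62820231 to 62850808) had 0 counts in the negative and 651 in the positive library, at least 239-fold lower. Rassf5 (569 counts), Phtf1 (542), Slc37a2 (523), Mpp3 (438), Pld4 (433), Zfp566 (404) and Emilin2 (398) were also at 0 in the negative library. Cx3cr1, the fractalkine receptor of macrophages and monocytes, had 3 counts against 1150 (log2 ratio −8.72, interval −11.00 to −7.17), and Frrs1 had 2 against 827. Dhx33 and Ralgapa2 had 1 count each in the negative library against 846 and 667. Genes with at most 3 counts in one library and at least 100 in the other numbered 793, of which 401 were seen in the negative and 392 in the positive library. Without genes at 3 or fewer counts in one library, 1200 and 1131 genes were past the rule.

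Gene lists fixed in advance were described by their members past the rule and by the median log2 ratio of negative over positive, set against 10000 random lists matched on mean expression. A list whose median lay outside the central 95% of the random medians is said to stand apart, which describes these libraries only.

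Blood transcription factors were lower in the negative library. In the haematopoietic transcription factor heptad, 4 of 7 measured members were past the rule, all lower in the negative library, and 3 were not past it. The median was −1.39, and 21 of 10000 random lists lay as low. Beside Gata2 and Runx1 (chromosome 16, 92601466 to 92826149), these were Lyl1, 5.08-fold lower (log2 ratio −2.34, interval −2.59 to −2.11), and Lmo2, 2.62-fold lower (log2 ratio −1.39, interval −1.53 to −1.24). Gata2 is counted here, in the GATA family and in the mast cell list. The sort on its reporter favours this direction, so Gata2 is not a finding in any of them. Tal1 (log2 ratio −1.04), Fli1 (−0.57) and Erg (−0.38) were not past the rule. Of 24 measured haematopoietic stem and progenitor genes, 7 were lower and 1, Kit, was higher in the negative library, and 16 were not past the rule, with a median of −0.90 (percentile 0.09). Gfi1b, a repressor needed for erythroid and megakaryocytic cells, had 0 counts in the negative and 252 in the positive library, at least 92.5-fold lower. Cd48 had 0 and 184 counts, at least 67.5-fold lower, Procr was 12.2-fold lower (35 and 389 counts) and Cd93 8.77-fold lower (400 and 3187 counts). In the GATA family, Gata1 (0 and 351 counts), Gata2, Gata3 (8.998-fold) and Gata6 (2.65-fold) were lower in the negative library. Gata4, with 318 counts and 1, and Gata5, 4.97-fold, were higher there, and the cofactor genes Zfpm1 (8 and 58 counts) and Zfpm2 (log2 ratio −0.79) were not past the rule. The 8 genes had a median of −1.89 (percentile 0.64), which lay between members that went both ways. Its middle members were Gata2 and Gata6 (log2 ratio −1.40), so the gene whose reporter was sorted on helps to set this median.

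Genes of megakaryocytes and myeloid cells were lower in the negative library. Of 19 megakaryocytic measured members 14 were lower in the negative library, 5 were not past the rule and 0 were higher, with a median of −3.21, and 0 of 10000 random lists lay as low. Rab27b had 7 and 631 counts (99.2-fold lower in the negative library), the platelet tubulin gene Tubb1 had 3 and 281 (log2 ratio −6.69, interval −8.97 to −5.13), and the platelet glycoprotein genes Gp5 and Gp1bb had 0 counts against 124 and 109. Over the 13 members above 3 counts in both libraries the median was −1.45. Among 22 measured macrophage genes 15 were lower and 1 was higher in the negative library, with a median of −1.95 (0 of 10000 random lists as low). Pf4 was 9.99-fold lower (15.5 and 154 CPM) and Timd4, a receptor for apoptotic cells, had 0 and 138 counts. Cd14 went the other way, with 126 and 0 counts. Of 17 measured granulocyte and monocyte progenitor genes 6 were lower in the negative library and 0 higher, with a median of −2.95 (percentile 0.09). These included S100a8 (0 and 187 counts), Fcgr3 (46.4-fold lower, 25 and 1053 counts), Csf2rb (0 and 96 counts) and Srgn (4.87-fold lower), and over the 10 members above 3 counts in both libraries the median was −0.94 (percentile 1.18). Only 6 of 19 mast cell, basophil and eosinophil genes were measured. Hdc, the enzyme that makes histamine (0 and 269 counts), Slc18a2 (5.19-fold) and Gata2 were lower in the negative library and Kit was higher, with a median of −2.37 (percentile 0.13), or −1.33 over the 4 members above 3 counts in both libraries. The median of −2.37 lay between its middle members, Slc18a2 and Gata2. Since the cells were sorted on the Gata2 reporter and Gata2 enters both medians, neither is free of the sort. Of 11 measured lymphoid genes, Cd79b (0 and 161 counts) and Gata3 were lower in the negative library and 9 were not past the rule, and the median of −0.56 did not stand apart (percentile 15.3) and was 0.074 over the 9 members above 3 counts in both libraries.

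Erythroid genes were split. Of 18 measured members 6 were lower in the negative library and 12 were not past the rule, with a median of −3.34 (0 of 10000 random lists as low). Gata1, the erythroid master regulator, was at least 129-fold lower, and Car1 and Hemgn had 0 counts in the negative library against 158 and 117. The embryonic globin genes, named after their values were seen, had higher values in the negative library without passing the rule: Hbb-y was at 143 and 85.9 CPM, Hbb-bh1 at 103 and 55.8 CPM and Hba-x at 79.2 and 35.0 CPM. Globin genes resemble each other, so reads could have been split or dropped in counting. The median of the list depended on members seen in one library alone. It was 0.48 (percentile 90.3) over the 9 members above 3 counts in both libraries, −0.069 (percentile 41.4) over the 13 with at least 100 counts, and 0.89 (percentile 98.1) over the 5 with a mean of at least 50 CPM.

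Endothelial genes were lower in the negative library in 12 of 24 measured members and higher in 0, with a median of −1.04 (interval over members −1.48 to −0.62, 0 of 10000 random lists as low). Emcn, an endothelial sialomucin, was at 253 and 893 CPM (3.52-fold lower, log2 ratio −1.82, interval −1.88 to −1.75), and 0.5% of the 200 genes nearest in expression differed by as much. Ecscr (4.75-fold), Ramp2 (3.93-fold) and Mmrn2 (3.38-fold) were lower as well. The arterial list had 7 of 17 measured members lower and 2 higher in the negative library, with a median of −1.30 (percentile 0.05). The Notch ligand gene Jag1 had 0 and 378 counts, Notch4 was 4.67-fold and Notch1 3.42-fold lower, and Cxcl12, a chemokine that guides blood progenitors, was 6.06-fold higher (329 and 54.3 CPM). Over the 14 arterial members above 3 counts in both libraries the median was −0.44 and the list no longer stood apart (percentile 6.33). Among 11 venous and lymphatic genes 4 were lower and 1 was higher in the negative library, with a median of −0.94 (percentile 0.07). Prox1, a regulator of lymphatic identity, was 6.85-fold lower, the scavenger receptor genes Stab2 and Stab1 were 5.14-fold and 2.43-fold lower, and Ackr3, a receptor for Cxcl12, was 2.89-fold higher. Named after their values were seen, Flt4 was the other venous and lymphatic gene that was lower (2.23-fold), and Dll4 the other arterial gene that was higher (2.44-fold).

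**Figure D2:**
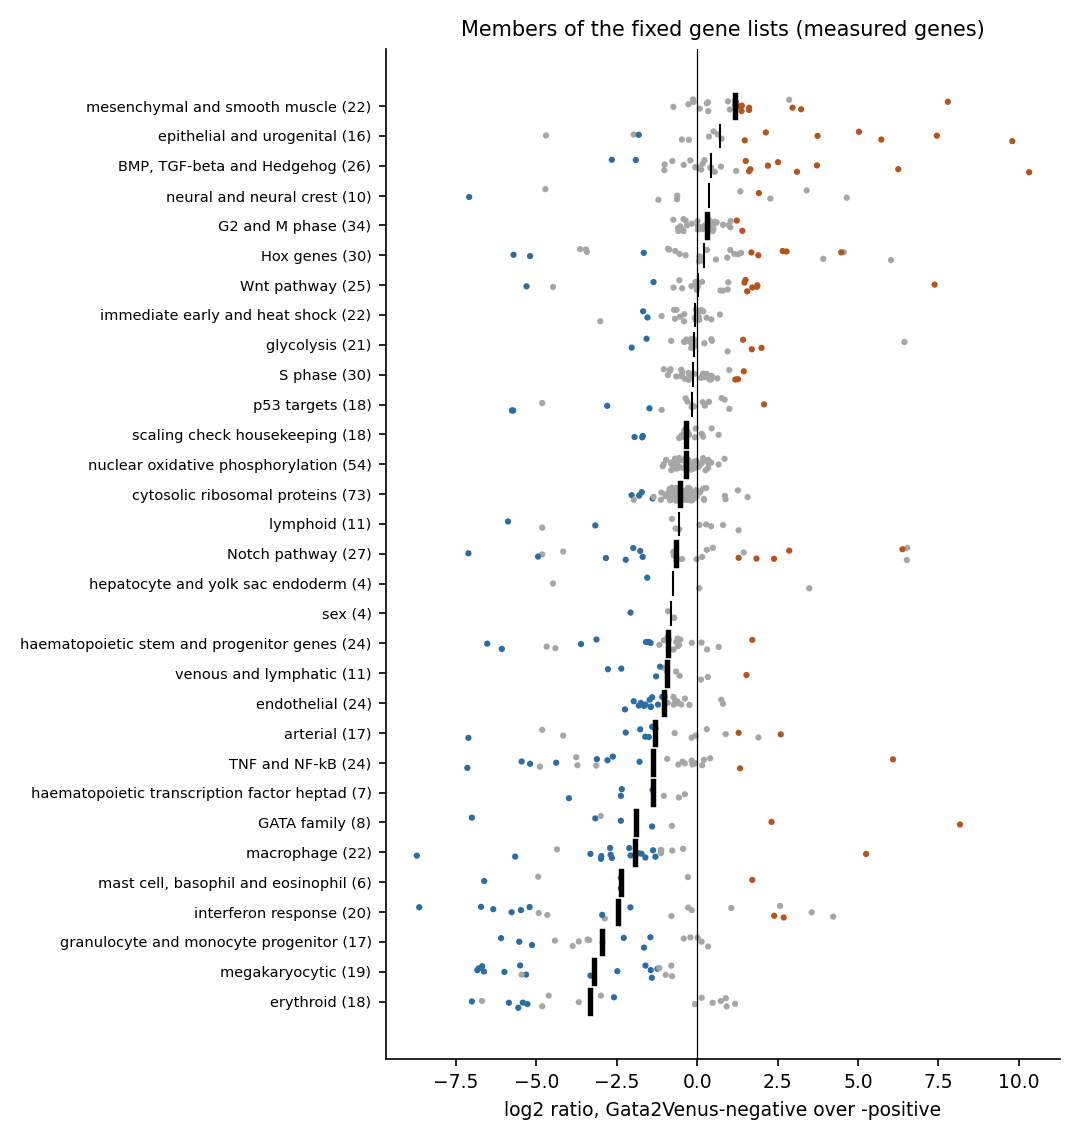
Members of each fixed list with at least 20 counts over both libraries, 1 point each, at the log2 ratio of the Gata2Venus-negative over the Gata2Venus-positive library; the number of measured members is in parentheses. Orange and blue points are past the rule of size, higher in the negative and in the positive library, and grey points are not; a bar marks the list's median, thick where it lay outside the central 95% of matched random lists. The erythroid median is lowest at −3.34 and the mesenchymal and smooth muscle median highest at 1.17.

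Mesenchymal and smooth muscle genes were higher in the negative library in 9 of 22 measured members and lower in 0, with a median of 1.17 (interval over members 0.30 to 1.61), and 0 of 10000 random lists lay as high. The pericyte gene Rgs5 had 489 and 2 counts (log2 ratio 7.80, interval 5.93 to 10.84), the limb and mesenchyme transcription factor gene Prrx1 was 9.40-fold higher, and Mfap4 was 3.06-fold higher (138 and 45.0 CPM). The collagen gene Col3a1, named after its values were seen, was at 3249 and 1310 CPM. The median level of the list's measured members was 141 CPM in the negative and 47.5 CPM in the positive library. Over the 14 members with a mean of at least 50 CPM the median log2 ratio was 0.68 and 0 of 10000 random lists lay as high. Of 26 measured genes of the BMP, TGF-beta and Hedgehog pathways 9 were higher and 2 lower in the negative library, with a median of 0.42 that did not stand apart (percentile 94.1). Beside Hhip, the Hedgehog receptor gene Ptch1 was 13.2-fold higher (597 and 41 counts), the transcription factor gene Gli2 8.60-fold higher (1023 and 108 counts), and Bmp7 had 168 and 2 counts. The Wnt pathway list had 7 members higher and 2 lower of 25 measured, and its median of 0.03 did not stand apart (percentile 51.6). Fzd7 was 3.66-fold and Dkk3 3.63-fold higher in the negative library, Wnt5b had 184 and 1 counts, and Fzd6 had 0 and 108. The other members lower in the negative library, named after their values were seen, were Bmpr2 (6.30-fold) and Tgfbr2 (3.76-fold) of the BMP and TGF-beta genes and Fzd4 (2.56-fold) of the Wnt genes.

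Notch pathway genes went both ways. Of 27 measured members 7 were lower and 5 higher in the negative library, with a median of −0.65 (percentile 1.68). The arterial list shares 7 of the 27, among them Jag1, Notch1, Notch4 and Dll4, so the 2 lists are not independent. Jag1, Dll1 (7.15-fold) and the coactivator gene Maml1 (30.9-fold, 10 and 281 counts) were lower, whereas Heyl, a Notch target, had 276 and 0 counts. Maml3 (7.27-fold), Dtx3 (5.24-fold), Notch3 (3.59-fold) and Dll4, named after their values were seen, were the other members that were higher. Of 30 measured Hox genes 5 were higher and 3 lower in the negative library, with a median of 0.22 (percentile 71.0). Hoxc6 (22.3-fold, 172 and 7 counts) and Hoxc9 (6.86-fold, 287 and 38 counts) were higher, and Hoxa2 had 0 counts in the negative against 100 in the positive library. Named after their values were seen, Hoxd10 (6.32-fold), Hoxc10 (3.73-fold) and Hoxc4 (3.22-fold) were also higher and Hoxa7 (3.16-fold) lower in the negative library.

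Interferon and inflammatory genes past the rule were more often lower than higher in the negative library, and neither list stood apart without members at or near 0 in one library. In the interferon response list 8 of 20 measured genes were lower and 2 higher, with a median of −2.48 (percentile 0.03). Stat2 had 1 and 364 counts (log2 ratio −8.65, interval −13.95 to −6.16), Rsad2 had 4 and 295, and Tap1 and Oasl2 had 0 against 149 and 122. Over the 10 members above 3 counts in both libraries the median was −0.22 (percentile 29.1). Over the 13 with at least 100 counts the interferon list still stood apart (median −2.08, percentile 0.02). In the TNF and NF-kB list 8 of 24 were lower and 2 higher, with a median of −1.36 (percentile 0.19). Tnf and Birc3 had 0 counts in the negative library against 100 and 120, and Tnfaip3, an inhibitor of NF-kB signalling, had 1 and 129. The adhesion molecule gene Vcam1 had 225 and 0. The other members higher in the negative library, named after their values were seen, were Tlr4 (2.52-fold) in this list and Irf9 (6.46-fold) and Ifitm1 (5.26-fold) in the interferon list. The TNF and NF-kB list did not stand apart over the 16 members above 3 counts in both libraries (median −0.42, percentile 8.97), over the 20 with at least 100 counts (−0.52, percentile 6.73) or over the 5 with a mean of at least 50 CPM (−0.39, percentile 15.1).

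Genes of the G2 and M phases had a median of 0.29, and 85 of 10000 random lists lay as high. Bub1, a spindle checkpoint kinase (2.65-fold), and Kif2c (2.35-fold) were past the rule on the negative side, and 32 of 34 members were not past it. S phase genes did not stand apart (median −0.14, percentile 15.3), although Dscc1 (2.73-fold) and Ung (2.27-fold) were among the members of 30 that were higher in the negative library. Cytosolic ribosomal protein genes were lower in the negative library, with a median of −0.52 over 73 measured members and 0 of 10000 random lists as low. Rpl12 (4.11-fold), Rpl31 (3.30-fold), Rpl10 (3.50-fold) and Rpl27a (2.62-fold) were past the rule, and 69 members were not, where 14.9% of all tested genes were past it on that side. These genes have many processed pseudogenes that share their reads, so their values are uncertain. Nuclear genes of oxidative phosphorylation had a median of −0.34 (percentile 0.18) with 0 of 54 members past the rule. The most abundant of them, Atp5b and Atp5a1, had log2 ratios of 0.19 and −0.14. The housekeeping genes of the scaling check had a median of −0.33 (percentile 2.36). A scaling offset moves the random lists alike, so it cannot set the percentiles of these lists, which stayed the same under total-count and DESeq2 scaling. It can still set where 0 lies. The distance from 0 of the oxidative phosphorylation median, and much of that of the ribosomal one, cannot be told apart from such an offset. Glycolysis genes did not stand apart (21 measured, median −0.09, percentile 28.3). Eno3 (4.005-fold), Hk2 (3.24-fold) and, named after its values were seen, Ldhb (2.69-fold) were higher and Pfkm (4.10-fold) and Pfkp (2.98-fold) lower in the negative library.

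Among genes that bear on other cell types and on RNA quality, 7 of 16 measured epithelial and urogenital genes were higher and 1 lower in the negative library, with a median of 0.70 (percentile 94.8). The higher ones included Dppa3, the germ cell genes Dppa4 (175 and 0 counts) and Ddx4 (193 and 1 counts), and the tight junction gene Cldn7 (108 and 0 counts). The lower one, named after its values were seen, was Cldn6 (3.53-fold). Over the 14 members with at least 100 counts the median was 1.12 and stood apart (percentile 99.0). These include Dppa3, Dppa4, Ddx4 and, named after its values were seen, Pou5f1 (870 and 59 counts). All of these are also in the germ cell list below, so this median does not stand for epithelial and urogenital genes alone. Of 10 measured neural and neural crest genes Map2 was 3.78-fold higher and Stmn2 lower (0 and 372 counts), with a median of 0.36 (percentile 70.0), or −0.63 (percentile 13.99) over members with at least 100 counts. Only 4 of 16 hepatocyte and yolk sac endoderm genes were measured: Apoe was 2.94-fold lower in the negative library, Trf (log2 ratio 0.06), Rbp4 (0 and 61 counts) and Amn (37 and 0 counts, named after its values were seen) were not past the rule, and the median was −0.75 (percentile 28.0). Immediate early and heat shock genes did not stand apart (22 measured, median −0.06, percentile 43.5), although Ier3 (3.21-fold) and Klf2 (2.92-fold) were lower in the negative library. Of 18 measured p53 targets 4 were lower and 1 was higher, with a median of −0.16 (percentile 32.6). Cdkn1a, a cell cycle inhibitor, was 6.96-fold lower, Perp had 0 and 148 counts, Trp53inp1 had 3 and 144, and Gadd45a was 4.23-fold higher. The other p53 target that was lower, named after its values were seen, was Phlda3 (2.80-fold). Both Xist, transcribed from the inactive X chromosome (118 and 194 CPM), and the Y-linked genes Ddx3y, Eif2s3y and Uty were present in both libraries. The 4 measured genes of the sex list had a median of −0.82 (percentile 9.65), with Eif2s3y 4.21-fold lower in the negative library. Housekeeping genes, included as a check of the scaling, had a median of −0.33 that stood apart (18 measured, percentile 2.36). Of these, B2m was 3.86-fold, Gusb 3.27-fold and Hprt 3.23-fold lower in the negative library, and 15 were not past the rule. Over the 15 with a mean of at least 50 CPM the median was −0.30 and the list did not stand apart (percentile 3.95). None of the mitochondrially encoded genes was measured, since 0 of their 28 listed names matched a gene of the count tables used here. The ribosomal RNA precursor Rn45s took 5.33% of the counts in the negative and 10.5% in the positive library, and the 100 most abundant genes took 18.9% and 23.6%.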

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

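Counts assigned to no gene made up a large part of both tables. The row for alignments that are not unique held 45.5% of all counts in the Gata2Venus-negative and 48.2% in the Gata2Venus-positive library. It holds reads with several alignments, some of which can lie in genes. The row for reads in no annotated feature held 5.93% and 7.996%. These rows are given because no comparison uses them and they hold counts, which by itself says nothing more about them.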

How the results depend on the processing

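The alternatives chosen only after the results were seen were leaving out genes at 3 or fewer counts in one library, and list members under a mean of 50 CPM. The level of Gata2 kept its direction and size under all 4 alternatives run on it, 16 counts of genes past the rule stayed within 1.5 times the reported ones, and 258 list medians kept whether they stood apart, with the lymphoid, neural and immediate early medians, which did not, changing sign under 1 alternative each. Of the ratios of named genes 535 stayed within their counting interval and 5 (Pecam1, Emcn, Stab1, Atp5b and Atp5a1, all under total-count scaling) moved out of it without changing sign. Counts of genes past the rule (higher in the negative, then in the positive library) were 629 and 545 with a filter of 50 CPM, 744 and 751 with an interval beyond 4-fold, and 641 and 683 with an assumed variation of 0.4 between libraries, where a stricter rule leaves fewer genes. The count on the positive side was 2484 with a filter of 1 CPM and 10 counts and 2503 with no filter, which test more genes. No scaling moved the share of genes on the negative side by over 10 percentage points (50.6% as reported, 55.1% under total-count scaling). Without genes at 3 or fewer counts in one library, the erythroid median changed sign to 0.48, and the arterial (−0.44), interferon (−0.22) and TNF and NF-kB (−0.42) lists no longer stood apart. With members of at least 100 counts, the erythroid (−0.069) and TNF and NF-kB (−0.52) lists no longer stood apart and the epithelial and urogenital list did (1.12). With members at a mean of at least 50 CPM, the erythroid median changed sign to 0.89, and the housekeeping (−0.30) and TNF and NF-kB (−0.39) lists no longer stood apart. For these 3 member filters, fewer members entered by construction, and no other cause was tested. No paired analysis was possible because each group holds 1 library, and leaving out a library was not possible for the same reason. Depth limits genes under about 10 CPM, where the interval of a 2-fold ratio is widest.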

Other observations

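Of the tests in this part, those on germ cell and urogenital ridge genes whose values had not been seen were written ahead of those values, and the others, with the lists of imprinted genes and of germ cell genes seen first, were chosen only after the result was seen.

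Germ cell genes were higher in the Gata2Venus-negative library. Of 25 measured genes of primordial germ cells and pluripotency, 19 were past the rule of size on the negative side and 0 on the positive side, with a median log2 ratio of 4.54, although the list was drawn up after many of these values were seen and 5 of its genes are in lists of the report. Sall4 was at 197 and 16.1 CPM (12.3-fold higher, log2 ratio 3.61, interval 3.38 to 3.86), Pou5f1, the pluripotency factor Oct4, at 83.6 and 6.24 CPM (13.4-fold), Tfap2c at 90.7 and 14.2 CPM (6.40-fold) and Utf1 at 93.2 and 1.69 CPM (55.1-fold). Prdm14 and Dnd1, which act in germ cell specification and survival, had 526 and 442 counts in the negative library and 0 in the positive. Zfp42 went the other way without passing the rule (11 and 40 counts). Nanos3 (39 and 21 counts) and Nanog (133 and 57 counts) were also not past it.

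Imprinted genes did not stand apart as a list (25 measured, median 0.18, percentile 88.3), with 3 higher and 0 lower past the rule in the negative library. Phlda2 was 43.0-fold higher (521 and 11 counts), Nnat 2.74-fold (371 and 136 CPM) and Peg3 2.25-fold (2046 and 909 CPM), whereas Mest, at 3616 and 4188 CPM, and Igf2, at 990 and 1709 CPM, were not past the rule.

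For the germ cell genes, a further 31 genes were listed before their values were seen. The 15 that were measured had a median log2 ratio of 4.72, and 0 of 10000 matched random lists lay as high (percentile 100), which argues against noise in single genes; 5 were past the rule, all on the negative side, namely Tcl1 (21.8 CPM) and Sox15 (18.8 CPM), both at 0 counts in the positive library, and Tdrd5, Rbm46 and Gdf3, while Tfcp2l1 (10 and 52 counts) and Rnf17 (91 and 92 counts) had lower values in the negative library. Germ cells in the Gata2Venus-negative gate may therefore be a source of these transcripts; mouse primordial germ cells carry CD31 and KIT, but no value here shows whether they pass a KITint gate, which would remove cells with more KIT. Of the listed genes, 12 of 28 in the first list and 2 of 31 in the second had more than 3 counts in the Gata2Venus-positive library. More urogenital ridge tissue cannot be told apart: 13 measured ridge genes had a median of 1.28 at percentile 94.4, between the outcomes set for and against it, although Amhr2 (0 and 52 counts), Sall1 (30 and 93) and Nr5a1 (16 and 33) had lower values in the negative library. Sorting on CD31 would remove ridge cells that lack it, which no value here measures, and expression of these genes in blood progenitors themselves stays open, untested.

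A second pattern is the 793 genes with at least 100 counts in one library and at most 3 in the other. In 100 simulated pairs of libraries with shared rates the highest number was 0, but this definition fixes that outcome and amplified reads are not independent molecules, so sampling of few molecules stays open. Of genes in the fixed cell type lists 14.3% were of this kind (23 of 161), against a median of 8.70% in matched random lists (percentile 99.9), so cell types held by one library alone may account for part of them. Transcripts lost before amplification, in genes of every kind alike, cannot be told apart: among genes of general cell machinery 2.45% (4 of 163: Pars2, Vps33b, Vps8 and Wars2) were of this kind, at percentile 84.4, and since 0 genes would have lain at percentile 3.57 the test had no way to exclude it.

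The third pattern is the opposite movement of blood and endothelial genes, lower in the negative library, and mesenchymal genes, higher there. It leaves out the lymphoid list, which did not stand apart (median −0.56, percentile 15.3), and the embryonic globin genes, which had higher values in the negative library. A lower share of blood cells would raise the other cell types alike, but the interval of the endothelial median ended at −0.62 and that of the mesenchymal median began at 0.30. These intervals treat genes as replicates and restate the pattern that led to the test. A lower share of blood cells stays open if blood cells also express the endothelial genes, which was not measured. A scaling factor moves all genes of a library alike, so it cannot open a gap between lists, whatever the values. The bounds, 0.92 apart, are thus no test of the scaling, which can still set where 0 lies between the lists. Without genes at 3 or fewer counts in one library, 8 of the blood and endothelial lists that stood apart still did (highest percentile 1.18), with smaller medians in some (megakaryocytic −1.45 after −3.21, granulocyte and monocyte progenitor −0.94 after −2.95), which argues against fully lost transcripts as the whole cause in those lists, but the erythroid (median 0.48, percentile 90.3) and arterial (−0.44, percentile 6.33) lists did not. There lost and absent transcripts cannot be told apart, since the filter drops the most changed members in either case. Gata2, on whose reporter the cells were sorted, is a member of the heptad and mast cell lists among the 8. Their medians were not taken without it. A different makeup of the cells in the 2 gates and a difference tied to Gata2 within the same cells both stay open and were not tested, and with 1 library each a difference between preparations was not tested either.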
